A study of Mus musculus with 5 samples.

How the data were processed

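RNA of sorted macrophages from 3 MyD88-ko and 2 WT samples was measured on Affymetrix mouse arrays. Per the labels' protocols, total RNA was extracted with TRIzol and 100 ng was made into biotin-labelled cDNA with a whole-transcript kit. The deposited table held log2 values normalized with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. The log2 scale was also read from the range of the values, which ran from 1.55 to 12.66 over the 5 arrays. RMA corrects background, normalizes between arrays by quantiles and summarizes the probes of each probe set. The genome build behind the probe sets is not given in the sources used here. Array medians lay between 4.33 and 4.42.

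Of 28846 rows, 19572 were probe sets paired with exactly 1 gene symbol in the platform annotation and 9274 had no gene there. No probe set had several symbols. The latter included 5222 negative and 1324 positive control probe sets, 63 spike-in, 23 antigenomic and 8 other control rows, and 2634 other transcript rows. Symbols were checked through gene identifiers against the RefSeq table of assembly GRCm38.p6, used only for names and for which genes neighbour Myd88. All 19572 matched and no symbol changed. For the 55 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19505 genes.

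The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 3 residual degrees of freedom), with genotype as the only term and the contrast MyD88-ko minus WT. P-values were adjusted with the Benjamini-Hochberg method over all genes, and a gene passed at an adjusted p under 0.05. No filter on dim probe sets was used. Differences are log2 and a fold is 2 to the power of the difference. SDs are over arrays. Intervals are 95% intervals of the fit.

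Gene lists (17, at least 5 measured members) and cell type marker lists (19, at least 3 measured members) were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted with Benjamini-Hochberg over each kind of list. Camera with a correlation estimated per list, and fry, were alternatives. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule named Myd88, Pdcd1, Cd274, Il1r1 and Il1b. It added the 10 steepest genes in each direction among those that passed with arrays that did not overlap, leaving out predicted genes, small RNAs, olfactory receptors and pseudogenes. Open places were filled by lowest p among genes with a fold of at least 1.5 and no overlap. It also added up to 4 members with the lowest p of each gene list and of each marker list that passed. Genes named beyond the rule were chosen after their values were seen: the called genes Trem1, Hcar2, Mxd1, Nlrp3 and Cxcr2, further members of the macrophage, neutrophil, monocyte and melanoma lists, and those of the closing section.

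The values used here came without detection calls. A background limit was therefore set, after the data were examined, at the 95th percentile of the negative controls of each array, and it lay between 6.55 and 6.96. A gene was taken as not above background in a group when it lay under the limit on all arrays of that group. For a gene above the limit in one group alone, the fold is given as "at least", from the bright group's mean and the dim group's mean of, per array, the higher of the limit and the gene's own value. No fold is given where both groups were under the limit or the bound was under 1. With log2 array values there is no read depth, and the limit takes its place as a strict measure of detection. Of 19505 genes, 14803 were above it on no array. The median of the positive controls was also under it on WT replicate 1 (6.51), WT replicate 2 (6.655) and MyD88-ko replicate 3 (6.70). Lying under the limit therefore does not show that a gene was not expressed. Positive controls were ranked above negative controls with an area under the curve of 0.831 and 0.834 on the WT arrays and 0.859, 0.861 and 0.849 on the MyD88-ko arrays.

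The alternatives were quantile normalization again, equal array medians, cyclic loess, 2 filters on level (the 25th and 50th percentile of all values), the mean of probe sets, trended and robust moderation, array weights, the replicate number as a block, the mean of Y-linked genes as a covariate, each array left out in turn, 2 other thresholds and a fit of all rows. A fit without neutrophil and monocyte markers and a fit of all transcript rows were added after the results were seen, as were the tests of marker lists with an estimated correlation and with fry. With 1 WT array left out, the lone WT array was assumed to vary like the MyD88-ko arrays. Replicate 3 exists only in MyD88-ko, so the fit with the block took no difference from that array. The mean of Y-linked genes was lower on every MyD88-ko array than on both WT arrays, so fits with it as a covariate cannot cleanly separate it from genotype.

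The fit was tested on simulated data with 200 changed genes in 5 runs over 19505 genes for this comparison. It recovered 57.6% of genes changed by 1 log2 unit, 95.8% by 2 and 98.8% by 4, and 30 of all 868 calls were false. All 5 moved lists and 0 of 100 unmoved lists were found. The simulated noise was independent between genes and held no background difference between the groups. These rates therefore need not hold for lists of co-expressed genes or for the real arrays.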

Results

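Tumour-associated macrophages (TAMs), the macrophages found in a growing tumour, were profiled on 5 single-colour whole-transcript expression arrays. Per the labels, 3 arrays held RNA from mice lacking MyD88 (MyD88-ko) and 2 held RNA from wild-type (WT) C57BL/6 mice. All mice had been engrafted under the skin with B16-F10 cells, a mouse melanoma line, and the cells were sorted at day 15 as positive for CD45, CD11b and the macrophage antigen encoded by Adgre1 and negative for CD3, B220 and NK1.1. The growth protocol names the spleen as the source of the sorted cells although every label calls them TAMs, and it allows mice of both sexes. The labels do not say whether the arrays came from separate mice, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. The arrays correlated with each other at Pearson r between 0.969 and 0.992 across the 19505 genes, and no array was a duplicate of another. WT replicate 2 correlated more closely with MyD88-ko replicate 3 (0.989) than with WT replicate 1 (0.986). MyD88 is the adaptor that carries signals from the IL-1 receptor family and most Toll-like receptors, and the series title names PD-1 expression as the outcome of interest. The question addressed by the comparison was which transcripts depended on MyD88 in these cells.

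The targeted gene, Myd88, was lower on all 3 MyD88-ko arrays (7.73, 7.01 and 7.58, log2) than on both WT arrays (8.46 and 8.40). The means were 7.44 ± 0.38 (SD, n = 3) and 8.43 ± 0.05 (SD, n = 2), a 1.99-fold difference that did not pass the test over all genes (limma, Benjamini-Hochberg adjusted p = 0.179). Signal for Myd88 stayed above the background limit on every array. The labels do not give the deleted exons, so whether its probes lie inside the deleted part is unknown. Pdcd1, which encodes PD-1, had means of 3.72 ± 0.14 (SD, n = 3) and 3.73 ± 0.06 (SD, n = 2). It lay under the background limit on all 5 arrays, between the 52.0th and 63.0th percentile of the negative-control probe sets, so its level could not be told from background. The difference for Pdcd1 was -0.01 on the log2 scale, with a 95% interval of -0.30 to 0.29. Cd274, encoding the PD-1 ligand PD-L1, was well above background at 7.79 ± 0.71 (SD, n = 3) in MyD88-ko and 8.89 ± 0.52 (SD, n = 2) in WT, and its log2 difference of -1.09 did not pass (limma, adjusted p = 0.373). Il1r1, the signalling receptor for IL-1, was under the background limit in both groups, with means of 2.96 and 3.13.

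Genes of inflammation and of neutrophils were among those lower in MyD88-ko cells than in WT cells. Of 19505 genes tested, 37 passed (limma, Benjamini-Hochberg adjusted p under 0.05), and 36 of these fell and 1 rose. All 37 had MyD88-ko and WT arrays that did not overlap, which passing with so few arrays all but requires. Of the 37, 6 are in the neutrophil marker list and 6 in the list of inflammatory genes, with Lcn2 in both. Among the genes that fell were S100a8 and S100a9, the calprotectin subunits of neutrophils and monocytes, and Lcn2, which encodes the iron-siderophore binding protein lipocalin 2. S100a9 averaged 4.63 ± 0.41 (SD, n = 3) against 9.11 ± 0.0022 (SD, n = 2), at least 5.60-fold lower (adjusted p = 0.0062). S100a8 was at least 3.67-fold lower (adjusted p = 0.029) and Lcn2 at least 4.21-fold lower (adjusted p = 0.0037). These 3 genes were under the background limit on all MyD88-ko arrays, so their folds are lower bounds. Il1b, encoding the cytokine IL-1β, was above background on all arrays and fell from 11.06 ± 0.39 (SD, n = 2) to 8.73 ± 0.35 (SD, n = 3), which was 5.02-fold lower (adjusted p = 0.041).

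Further lower bounds came from Retnlg, a resistin-like gene of granulocytes, at least 5.35-fold lower, and Hdc, which makes histamine, at least 6.89-fold lower. Hp (haptoglobin) was at least 3.93-fold lower, the decoy receptor Il1r2 at least 3.53-fold, and Trem1, an amplifier of myeloid inflammation, at least 3.04-fold. Mrgpra2b was at least 2.05-fold lower. Ifitm1 fell 5.70-fold, Hcar2 4.13-fold and Mxd1 3.70-fold, all above background on every array. Il1f9, an IL-1 family cytokine, passed with means of 3.69 ± 0.11 (SD, n = 3) and 6.56 ± 0.16 (SD, n = 2) that were under the background limit in both groups, and Stfa2l1 passed likewise with means of 2.93 and 6.00. Altogether 14 of the 37 genes were under the limit on all arrays, against 14803 of all 19505 genes. Of the 37, 10 were above it on all arrays, and the other 13 were under it on all MyD88-ko arrays and above it on at least 1 WT array. The single gene that rose was Sgcb, a sarcoglycan subunit, with means of 6.17 and 5.09, both under the limit (limma, adjusted p = 0.039). The next genes in the higher direction did not pass. Rrm2 and Tmem97 had log2 differences of 0.91 (adjusted p = 0.076) and 0.78. Dhcr7 was at least 1.55-fold higher (adjusted p = 0.082), and Siglec1, at 6.86 and 6.05, was likewise under the limit on both WT arrays. Ephx1 (6.48 and 5.44, adjusted p = 0.051), Hvcn1 (5.59 and 4.19, adjusted p = 0.079), Mr1 (5.20 and 4.35), Mtbp (6.07 and 5.38) and Mid1ip1 (5.93 and 5.15) were under the limit on all arrays.

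Over all genes, 2449 had an unadjusted limma p under 0.05, of which 1202 were higher, and 5414 genes (27.8%) had groups that did not overlap, where chance gives 20%. The count of 37 depended on having all 5 arrays: limma called 1 gene without MyD88-ko replicate 2 and 0 without each of the other 4 arrays in turn, with 1691 to 3762 genes at an unadjusted p under 0.05. All 37 genes kept their sign in each of these 5 runs, and an unadjusted limma p under 0.05 without each MyD88-ko array in turn. The runs reuse arrays on which the genes were picked, so this was close to fixed by that choice. The WT arrays had the higher background: the 95th percentile of the negative controls was 6.91 and 6.96 in WT against 6.55, 6.59 and 6.74 in MyD88-ko, and 3420 and 3480 genes were above it in WT against 4334, 4194 and 3968. In a limma fit of genes and negative controls together, chosen after the results were seen, 813 of 5222 controls were lower in MyD88-ko at an unadjusted p under 0.05, against 1125 of 19505 genes. At the highest p of the 36 genes called lower there were 2 such controls, and 0 controls and 3 genes passed an adjusted p of 0.05 in that fit.

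**Figure D1:**
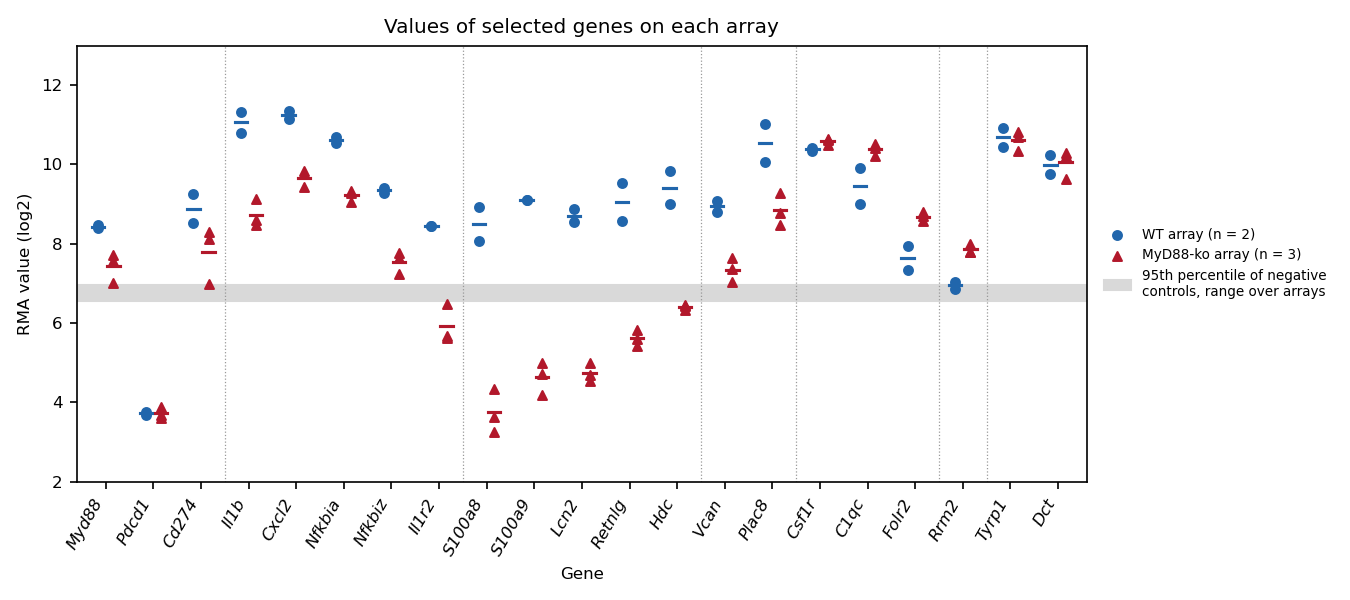
Log2 values of selected genes (x axis) on each array (y axis), with WT arrays as blue circles (n = 2), MyD88-ko arrays as red triangles (n = 3), short bars for group means and a grey band for the range over arrays of the 95th percentile of negative controls. S100a8, S100a9 and Lcn2 lie above the band in WT and below it in MyD88-ko, while Pdcd1 lies below it on every array; Csf1r, Tyrp1 and Dct were chosen after their values were seen.

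The NF-κB and inflammatory cytokine genes fell as a group. Of 48 measured genes, 47 had negative differences and the median was -0.97 on the log2 scale (camera, adjusted p = 6.2e-34; adjusted p = 0.23 with an estimated correlation). Of these genes, 6 passed over all genes, all lower, and 34 were lower adjusted over the list alone. Besides Lcn2 and Il1b, the 6 included the chemokine Cxcl2, 2.98-fold lower, Nfkbiz, 3.47-fold lower, and the NF-κB inhibitor Nfkbia, 2.64-fold lower. The inflammasome sensor Nlrp3 was also among the 6, 2.72-fold lower. Cxcl2, Nfkbiz, Nfkbia and Nlrp3 had adjusted p between 0.034 and 0.039 (limma). Among the immediate early and heat shock genes, 22 of 25 had negative differences with a median of -0.55 (camera, adjusted p = 4.1e-15; adjusted p = 0.21 with an estimated correlation). Gadd45b, a stress-response gene, fell 2.34-fold and Dusp2, a MAP kinase phosphatase, had means of 4.85 and 6.20 under the limit. These were the 2 genes of that list that passed over all genes, and 16 were lower and 1 higher adjusted over the list alone. Ier2 (-0.86) and Hspa1a (-0.92) did not pass over all genes.

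The MyD88 pathway components also fell as a group, with a median of -0.31 over 30 measured genes, 24 of them negative (camera, adjusted p = 1.2e-07; adjusted p = 0.23 with an estimated correlation). Il1r2 and Il18rap, an IL-18 receptor chain under the limit on all arrays at means of 4.27 and 5.92, were the 2 that passed over all genes, and 11 were lower and 1 higher adjusted over the list alone. Irak3, a brake on IL-1 and Toll-like receptor signalling, and the receptor Tlr2 had log2 differences of -0.81 and -0.67 that did not pass. The 29 measured genes that flank Myd88 on chromosome 9 did not pass as a group (camera, adjusted p = 0.712), with a median of 0.04, a mean of -0.03 and a camera direction of lower. None of the 29 passed over all genes, and 2 were lower adjusted over the list alone. Csrnp1 and Epm2aip1 had the lowest p-values there, Csrnp1 with a log2 difference of -0.80 and Epm2aip1 with means of 6.06 and 6.64, under the limit on all arrays. Of the 29 genes, 24 were under the limit on all arrays.

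Neutrophil and monocyte markers were lower in MyD88-ko; the tests of marker lists with an estimated correlation were chosen after the results were seen. The 15 measured neutrophil markers had a median of -1.94 (camera, adjusted p = 8.4e-14; adjusted p = 0.31 with an estimated correlation), and 6 fell over all genes and 9 adjusted over the list alone. Besides S100a8, S100a9, Lcn2, Retnlg and Stfa2l1, the sixth was the chemokine receptor Cxcr2, with means of 4.34 and 6.62 and under the limit on all MyD88-ko arrays. Csf3r, the G-CSF receptor, was at 7.65 and 9.59 and did not pass (limma, adjusted p = 0.051). The granule genes of immature neutrophils were near background in both groups, with Camp at 3.53 and 3.65, Ngp at 3.26 and 3.59, and Ltf at 3.14 and 3.04. The 9 classical monocyte markers had a median of -1.70 (camera, adjusted p = 1.4e-07; adjusted p = 0.34 with an estimated correlation), with Hp the 1 gene lower over all genes and 7 lower adjusted over the list alone. Vcan (-1.60), Plac8 (-1.70) and Chil3 (at least 1.55-fold lower) did not pass over all genes. The 9 non-classical monocyte markers had a median of -0.96 (camera, adjusted p = 8.3e-05; adjusted p = 0.34 with an estimated correlation; -0.45 without WT replicate 1). Nr4a1 had a log2 difference of -0.96 in that list, and Ace, Treml4 and Itgal, under the limit on all MyD88-ko arrays, were at least 1.09-fold, 1.47-fold and 2.02-fold lower. Of the 9 markers, 5 were under the limit on all arrays, none passed over all genes and 4 were lower adjusted over the list alone.

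Macrophage markers did not pass as a group. The 12 measured genes had a median of 0.27 (camera, adjusted p = 0.484), and of 0.12 without WT replicate 1 (adjusted p = 0.668). None passed over all genes, and 4 were higher and 2 lower adjusted over the list alone. The complement genes C1qa, C1qb and C1qc had log2 differences of 0.68, 0.56 and 0.94. Adgre1, whose product the sort selected for, was at 9.20 and 8.82, Csf1r at 10.59 and 10.38, and Lyz2 at 11.59 and 11.58. The 18 complement and Fc receptor genes had a median of 0.08 and did not pass (camera, adjusted p = 0.388), with no gene passing over all genes or adjusted over the list alone. Markers of B16 melanoma cells were abundant in both groups despite the CD45 gate: over the 5 arrays Tyrp1 lay between 10.34 and 10.92, Dct between 9.65 and 10.29, and Pmel between 9.07 and 9.88. The 12 measured melanoma markers had a median of 0.16 and did not pass (camera, adjusted p = 0.153), although they passed without MyD88-ko replicate 2 (0.28, adjusted p = 0.0056) and without WT replicate 1 (0.41, adjusted p = 8.8e-04). Without WT replicate 2 the median was 0.014 (camera direction lower, adjusted p = 0.862), and with the mean of Y-linked genes as a covariate 0.0010 (direction lower, adjusted p = 0.501).

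**Figure D2:**
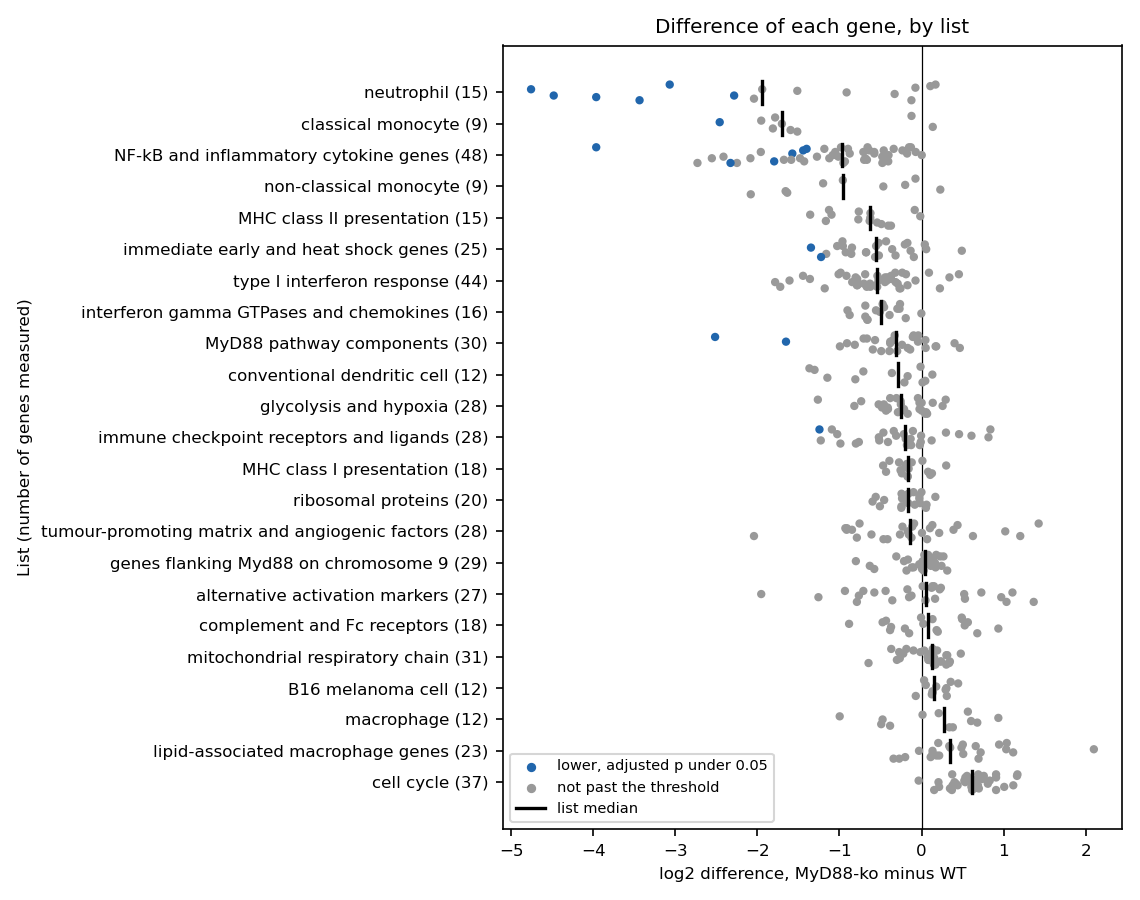
Log2 difference (MyD88-ko minus WT, x axis) of each measured gene in the 17 gene lists and 6 marker lists (y axis, number of measured genes in parentheses), with genes lower at an adjusted p under 0.05 in blue, other genes in grey and list medians as black bars. The neutrophil median of -1.94 lies lowest and the cell cycle median of 0.61 highest.

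Cell cycle genes were higher as a group in MyD88-ko. Of 37 measured genes, 36 had positive differences, with a median of 0.61 (camera, adjusted p = 5.5e-17; adjusted p = 0.37 with an estimated correlation). No cell cycle gene passed over all genes and 19 were higher adjusted over the list alone. Of the 37 genes, 17 were under the background limit on all arrays, and the 6 above it on all arrays had a median of 0.62. Rrm2, a ribonucleotide reductase subunit, had a log2 difference of 0.91. E2f8 (6.08 and 4.91), the mitotic kinase Aurka (6.23 and 5.62) and the spindle checkpoint kinase Bub1 (5.97 and 5.28) were under the limit on all arrays. The lipid-associated macrophage genes had a median of 0.35 with 19 of 23 positive (camera, adjusted p = 9.9e-05; adjusted p = 0.56 with an estimated correlation). None of them passed over all genes and 1, Gpnmb, was higher adjusted over the list alone. Log2 differences were 0.72 for Gpnmb, 1.03 for lipoprotein lipase (Lpl), 1.04 for lysosomal acid lipase (Lipa) and 0.50 for Cd63. Without WT replicate 1 the median of this list was 0.17 and it did not pass (adjusted p = 0.086), and without WT replicate 2 it was 0.67.

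MHC class II presentation and type I interferon genes were lower as groups, by amounts that depended on single arrays and on the Y-linked covariate. The 15 MHC class II presentation genes all had negative differences, with a median of -0.62 (camera, adjusted p = 9.7e-07; adjusted p = 0.50 with an estimated correlation; -0.31 without WT replicate 1, -0.95 without WT replicate 2 and -1.39 with the Y-linked covariate). Markers of 2 other kinds of antigen-presenting cell were also lower as groups by camera. Conventional dendritic cells were at -0.29 (camera, adjusted p = 0.0022, and 0.62 with an estimated correlation). Classical monocytes were at -1.70 (camera, adjusted p = 1.4e-07, and 0.34 with an estimated correlation). The costimulatory genes Cd80 and Cd86 had log2 differences of -1.36 and -1.17, and the class II transactivator Ciita, under the limit on all MyD88-ko arrays, had means of 5.30 and 6.42. None of the 15 passed over all genes and 1, Cd80, was lower adjusted over the list alone. The 44 type I interferon response genes had a median of -0.54 with 40 negative (camera, adjusted p = 9.0e-09; adjusted p = 0.59 with an estimated correlation). It was -0.31 without MyD88-ko replicate 2, -0.15 without WT replicate 1, -1.002 without WT replicate 2 and -0.996 with the Y-linked covariate. Ifi209 (-1.72), Oas2 (-1.36) and Isg20 (under the limit on all MyD88-ko arrays) were among those with the lowest p-values, and no gene of the list passed over all genes or adjusted over the list alone.

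The 16 interferon gamma GTPases and chemokines had a median of -0.49 (camera, adjusted p = 0.0032; adjusted p = 0.64 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The direction turned without WT replicate 1, where the median was 0.22 (adjusted p = 0.771), and the list did not pass without MyD88-ko replicate 2 (-0.22, adjusted p = 0.172). The median was -0.75 without MyD88-ko replicate 3, -1.28 without WT replicate 2 and -1.09 with the Y-linked covariate. Fcgr1 had a log2 difference of -0.47 and Irf1 of -0.66. The 18 MHC class I presentation genes had a median of -0.17 and did not pass (camera, adjusted p = 0.105), with none passing over all genes or adjusted over the list alone. They passed without MyD88-ko replicate 3 (-0.23, adjusted p = 0.026) and without WT replicate 2 (-0.39, adjusted p = 0.0013), but the median was -0.080 without MyD88-ko replicate 2 and turned to 0.024 without WT replicate 1. They also passed as lower with cyclic loess (adjusted p = 0.041) and with the Y-linked covariate (adjusted p = 0.0031). Calr had a log2 difference of 0.30 and Psme1 of -0.47.

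The 28 immune checkpoint receptors and ligands had a median of -0.20 with 22 negative (camera, adjusted p = 2.3e-04; adjusted p = 0.21 with an estimated correlation). Nt5e, encoding the adenosine-producing enzyme CD73, was the 1 gene that passed over all genes, with means of 4.32 and 5.57 under the limit in both groups. Adjusted over the list alone, 2 were higher and 8 lower. The median was -0.32 and -0.41 with the filters on level at the 25th and 50th percentile. Lilrb4a had a log2 difference of -0.52. Siglec1 was at 6.86 and 6.05, under the limit on both WT arrays, and Tnfsf4 at 3.69 and 4.71, under it on all arrays. The 27 alternative activation markers had a median of 0.05, a mean of -0.03 and a camera direction of lower, and did not pass (adjusted p = 0.537), although they passed as lower without MyD88-ko replicate 3 (-0.17, adjusted p = 0.048), without WT replicate 1 (-0.28, adjusted p = 0.011) and with the Y-linked covariate (-0.28, adjusted p = 0.018). Without WT replicate 2 the camera direction was higher (0.13, adjusted p = 0.070), and without MyD88-ko replicate 2 the median was 0.11. Folr2, a marker of resident macrophages, had a log2 difference of 1.03 in that list and Pdcd1lg2 of -0.76. Chil3 was at 5.31 and 7.26, under the limit on all MyD88-ko arrays, and Il10 was under it on all arrays. None passed over all genes, and 1 was higher and 2 lower adjusted over the list alone.

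The 28 tumour-promoting matrix and angiogenic factors had a median of -0.14 and did not pass (camera, adjusted p = 0.114), with 0 genes passing over all genes and 3 higher and 5 lower adjusted over the list alone. They passed without MyD88-ko replicate 3 (-0.22, adjusted p = 0.028) and without WT replicate 1 (-0.35, adjusted p = 0.0098), but the median was -0.013 without MyD88-ko replicate 2 and 0.016 without WT replicate 2. They also passed as lower after quantile normalization (adjusted p = 0.039), with equal medians (adjusted p = 0.029) and with the Y-linked covariate (adjusted p = 0.035). Plaur had a log2 difference of -0.79 and Thbs1 of -0.91. Mmp9, under the limit on all MyD88-ko arrays, was at least 1.08-fold lower, and Vegfb, at 6.15 and 5.52, was under it on all arrays. The 28 glycolysis and hypoxia genes had a median of -0.25 (camera, adjusted p = 0.0062; adjusted p = 0.64 with an estimated correlation), with none passing over all genes or adjusted over the list alone. This list did not pass without MyD88-ko replicate 2 (0.03, adjusted p = 0.821) or without WT replicate 2 (-0.14, adjusted p = 0.468), and its median was -0.39 without MyD88-ko replicate 1 and -0.50 with the Y-linked covariate (adjusted p = 1.3e-04). Hif1a and Egln3 had log2 differences of -0.74 and -1.26. The 20 ribosomal protein genes had a median of -0.16 (camera, adjusted p = 0.0032; adjusted p = 0.64 with an estimated correlation), -0.31 without WT replicate 2 and -0.0053 without WT replicate 1, where they did not pass (adjusted p = 0.479), nor with the Y-linked covariate (-0.12, adjusted p = 0.0998); the median was -0.10 with equal array medians. Rpl22 had a log2 difference of -0.56. The 31 mitochondrial respiratory chain genes had a median of 0.13 and did not pass (camera, adjusted p = 0.201), with a median of 0.050 without WT replicate 1, and Cox6c had a log2 difference of -0.65. In both of these lists no gene passed over all genes or adjusted over the list alone. Of the 17 gene lists, 11 passed camera with the preset correlation, 0 with an estimated one, and 3 passed fry, a test of whether a list moves one way: the inflammatory, checkpoint and immediate early lists.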

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

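The test of monocyte and macrophage inflammatory genes, with its limit on the upper quartile, the tests of the negative controls against the 16 genes with smaller falls and both tests of the cell cycle genes were chosen after the results were seen. Among the 2634 transcript rows that have no gene name here, 4 passed an adjusted p of 0.05 in a limma fit of the named and unnamed transcripts, a signal in data outside the comparison of named genes. All 4 were lower in MyD88-ko, with log2 differences between -2.75 and -1.22 and adjusted p between 0.034 and 0.043. Of the 10 splits of the 5 arrays into 3 and 2, 1 (the real one) gave as many as 37 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

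Neutrophil markers were lower in MyD88-ko cells. A second list of 26 genes chosen as those of mature neutrophils had a median log2 difference of -0.56. In it 23 genes were negative and 0 passed the adjusted threshold in limma. Of these genes, 1 is in another list and 8 were above the background limit on all MyD88-ko arrays. The median was lower than all of 10000 random lists matched on level. Those lists were drawn gene by gene and lack the shared movement of co-expressed genes, so they do not measure how sure the fall is. In the first list S100a9, Retnlg and Csf3r averaged 9.11, 9.05 and 9.59 in WT. More neutrophil RNA in the WT sorted cells is a candidate explanation. The second list cannot tell it from expression of these genes by other cells. Neutrophils also carry little of the antigen encoded by Adgre1, and the gate for it should remove them. Melanoma markers were abundant on all arrays despite the CD45 gate, however, so the gates alone do not exclude neutrophil RNA. Expression of the same genes by WT monocytes and macrophages stays open as a biological explanation and was not tested.

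Inflammatory genes were lower in MyD88-ko cells. A set of 14 genes, chosen as made mainly by monocytes and macrophages, had a median of -0.62 and an upper quartile of -0.16. Of these, 13 are also in another list. Only 5 were above the background limit on all MyD88-ko arrays, and the median of the others was -0.93. The median alone would go against fewer neutrophils as the sole cause, but the members went both ways, so it cannot decide. Acod1 was at -2.73 and Ccl5 at -1.18, against Ccl2 at -0.13 and Ccl8 at 0.73. Classical monocyte markers were also lower, with a median of -1.70. The 14 genes therefore cannot separate expression per cell from the mix of sorted cells. The higher background of the WT arrays was weighed as a cause for the 36 genes called lower. The 980 matched negative controls had a median of -0.22 against -1.95, and 20 of the genes fell further than every one of these controls. The genes were picked for their fall and the controls were not, so that contrast was largely set by the choice. Counted over all genes and controls after the results were seen, 35 of 19505 genes and 1 of 5222 controls were at -1.95 or lower. Falls of that size were thus rarer among controls than among genes. The cutoff was the median of the called genes, however, and these controls were not matched on level, so background is not excluded. At an unadjusted limma p under 0.05, 813 of 5222 controls were lower, against 1125 of 19505 genes. Of the other 16, 5 were above the limit on all arrays (Cxcl2, Nfkbia, Stk17b, Gadd45b and Nlrp3, median -1.44). The lowest of 184 controls above the limit was at -1.20, but these 5 genes were also picked for their fall, so this cannot decide. Background cannot be told apart as a cause for the 11 dimmer ones either. Of 470 controls at their level, 1.06% fell by as much as the median of these 11, -1.35, and the 5th percentile was -1.07. A loss of MyD88-dependent transcription, which the design names, stays open.

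Cell cycle genes were higher as a group in MyD88-ko cells by camera (adjusted p = 0.37 with an estimated correlation), with a mean difference of 0.62 (95% interval -0.018 to 1.25), and in limma 0 passed over all genes and 19 were higher adjusted over the list alone. The gap between the cell cycle and melanoma marker means differed by 0.42 between genotypes, with a 95% interval of -0.93 to 1.77, so more melanoma RNA cannot be told apart from more cycling macrophages with 5 arrays. The gap to 7 macrophage-restricted markers, chosen after their values were seen, moved by 0.085 (-0.25 to 0.42), and that to the macrophage list of 12 genes by 0.50 (-0.024 to 1.03). Those 7 had a mean difference of 0.53 (-0.12 to 1.18) and the 12 of 0.11 (-0.049 to 0.28), so dilution of WT macrophages by other myeloid cells cannot be told apart from a change in cycling. An effect of MyD88 on proliferation stays open as a biological explanation.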

How the results depend on the processing

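The fits without neutrophil and monocyte markers and of all transcript rows, and the tests of marker lists with an estimated correlation and with fry, were chosen after the results were seen. Against 37 genes called, cyclic loess gave 63, array weights 15, an adjusted p under 0.1 gave 84, an unadjusted p under 0.05 with a fold of 1.5 gave 1007, and a fit of all rows of the table, which tests more rows, gave 3. The mean of Y-linked genes as a covariate gave 0 (1818 at an unadjusted p under 0.05 in limma), and leaving out single arrays gave 0 to 1, both with fewer degrees of freedom. The Y-linked mean was lower on every MyD88-ko array than on both WT arrays, so the fit with that covariate is not a clean adjustment for sex. Without neutrophil and monocyte markers 11 genes were called, all among the 37. In that fit 1 marker list passed, as 3 of the 4 that had passed were removed by construction. Only 7 of the 37 genes were removed. The other 30 had to keep their differences exactly, as each gene is fitted on its own. Those no longer called had adjusted p between 0.0501 and 0.0537 in limma. Leaving out marker genes does not remove RNA of those cells, so this fit does not bear on the mix of sorted cells. The other 7 settings gave 37 to 55 genes. The labels do not tie equal replicate numbers, so the numbers were not taken as pairing. Same-numbered arrays deviated from their group means with correlations of 0.059 and 0.105. With 2 WT arrays the WT deviations mirror each other, so these values can neither show nor exclude pairing. With the replicate block 70 genes were called, 29 of them among the 37. Replicate 3 exists only in MyD88-ko, so the block gave that array a term of its own. The differences were therefore those without MyD88-ko replicate 3, with a median over all genes of 0.022 in both fits. With an estimated correlation 0 gene lists and 0 marker lists passed, and with fry 3 gene lists and 6 marker lists. With the replicate block MHC class I (adjusted p = 0.0023), matrix factors (0.013), NK cell (0.031) and fibroblast (0.026) lists passed, and the interferon gamma median was -0.75. Pdcd1, near -0.01, turned to 0.035 after quantile normalization, 0.054 with equal medians, 0.011 with cyclic loess, 0.015 with the replicate block and 0.037 with the Y-linked covariate, and ranged from -0.084 to 0.052 without single arrays. List medians that changed sign did so mostly without single arrays: interferon gamma genes ranged from -1.28 to 0.22, MHC class I from -0.39 to 0.024, alternative activation from -0.28 to 0.13, matrix factors from -0.35 to 0.016, glycolysis from -0.39 to 0.035, complement from -0.0087 to 0.13 and Myd88 neighbours from -0.0074 to 0.048. Alternative activation was at -0.17 with the replicate block, which is the same difference as without MyD88-ko replicate 3. With the Y-linked covariate alternative activation was at -0.28 and complement at -0.042. Marker lists with medians near 0 did the same without single arrays: platelets reached 0.0089, mast cells or basophils ranged from -0.054 to 0.089, plasma cells from -0.098 to 0.11, B cells from -0.15 to 0.038, erythroid cells from -0.047 to 0.067, endothelial cells from -0.025 to 0.022 and keratinocytes from -0.049 to 0.028. Apart from the fewer samples or more rows named above, the cause was not tested. All 37 genes kept their direction without each array in turn, in runs that reuse arrays on which they were picked. Signal over background limits Pdcd1, Il1r1 and the 14 called genes under the limit on all arrays.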

Other observations

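The tests of marker lists with an estimated correlation and with fry were chosen after the results were seen. Conventional dendritic cell markers fell as a group, with a median of -0.29 over 12 genes (camera, adjusted p = 0.0022; adjusted p = 0.62 with an estimated correlation), but did not pass without WT replicate 1 (-0.25, adjusted p = 0.076), and the median was -0.47 without WT replicate 2, -0.61 with the Y-linked covariate (adjusted p = 1.5e-04) and -0.54 with either filter on level. Fscn1 was at least 1.54-fold lower, and Flt3 (3.56 and 4.37) and Kmo (3.23 and 4.53) were under the background limit on all arrays. None passed over all genes and 3 were lower adjusted over the list alone. NK cell markers had a median of -0.11 (adjusted p = 0.058; adjusted p = 0.046 after quantile normalization), with Klrd1 lower at means of 2.89 and 4.60, both under the background limit, and Ncr1 at 2.53 and 2.65. Mast cell or basophil markers had a median of 0.03 and a mean of -0.41 (camera direction lower, adjusted p = 0.543), in which Hdc fell while Mcpt8 (3.29 and 3.18) and Cpa3 (3.04 and 3.02) were near background. With fry the T cell list passed as higher (adjusted p = 0.013) and the NK cell and mast cell or basophil lists as lower (both adjusted p = 0.037), although 11 of 12, 11 of 11 and 8 of 9 of their genes were under the limit on all arrays.

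Medians of the other marker lists, none of which passed camera, were -0.10 for eosinophils (adjusted p = 0.587), 0.11 for plasmacytoid dendritic cells (0.543), 0.04 for T cells (0.543) and -0.15 for platelets (0.506). B cell markers had a median of -0.06 and a mean of 0.06 (0.804), plasma cell markers 0.05 and -0.12 (0.799), erythroid markers 0.0082 and 0.06 with a camera direction of lower (0.804), endothelial markers 0.0050 and -0.05 (0.804) and keratinocyte markers -0.0071 and 0.0029 (0.804). Fibroblast markers had a median of -0.20 (0.289) and passed as lower without MyD88-ko replicate 1 (-0.34, adjusted p = 0.027), but the median was -0.022 without MyD88-ko replicate 2 (adjusted p = 0.813), -0.027 without WT replicate 1 (adjusted p = 0.931), -0.12 without MyD88-ko replicate 3 and -0.35 without WT replicate 2. The median of each marker list in this part that lay within 0.15 of 0 moved by over 1.5 times or turned sign without at least 1 single array.

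The growth protocol names the spleen, and genes of splenic red pulp macrophages had a median of 0.23 and did not pass (camera, adjusted p = 0.799). The median was 0.024 without WT replicate 1 (camera direction lower), 0.39 without MyD88-ko replicate 2 and 0.43 without WT replicate 2. That test compares genotypes, so it does not bear on which tissue was sorted. Spic, the regulator of red pulp macrophages, was under the background limit on all arrays, with means of 3.49 in MyD88-ko and 5.16 in WT. Cd5l was at 4.99 and 4.43, while Hmox1, which many macrophages express, was at 11.75 and 11.50. Melanoma markers were abundant, with array medians between 7.50 and 8.37, which goes with tumour as the source, but no reference tissue was compared. The mean of 3 Y-linked genes was 5.51, 5.51 and 4.59 on the MyD88-ko arrays and 5.89 and 6.03 on the WT arrays, and Xist was not measured here.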
